A study of Felis catus with 6 samples.

How the data were processed

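The series holds 6 polyA RNA-seq libraries of the feline kidney cell line PETCC2610 in 2 groups of 3. The first group is named DOX after the agent used to make the cells senescent, and the second, DOX+PeptideE, received the same agent together with a peptide that the series title traces to a Bifidobacterium adolescentis fermentation. The labels do not spell out the abbreviation DOX and give neither doses nor times. Libraries were placed in their groups by their titles, and replicate numbers were taken from the same titles. The series text describes the 3 libraries of a group as biological replicates without saying how the cultures were separated. The p-values of single genes therefore measure the spread between these libraries.

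Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured on oligo(dT) beads, fragmented and copied with random primers, and the libraries were sequenced as pairs of 150 bp on a NovaSeq instrument. The submitters' processing notes name FastQC 0.11.9 and fastp 0.19.5. The aligner, the genome build and the annotation are not given in the sources used here, and the name of the deposited table refers to RSEM as the tool of quantification. Whether reads were counted by strand is not stated either.

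A single deposited table was analysed, with 633 genes. Its 6 library columns hold a normalized expression signal that the authors computed per gene and library, with 2 decimals and no unit in the header. Whether this deposited signal is TPM or FPKM is not stated, so it is called the expression value throughout. The authors' 2 group columns equal the arithmetic means of these library values. The table also holds the authors' fold change of DOX+PeptideE over DOX, its log2 value, and the authors' unadjusted and adjusted p-values. Each gene in the deposited table is marked significant by the authors. Tested on the table itself, every gene has an unadjusted p-value of at most 0.0498 and a fold change of at least 1.5 in either direction. No column of any other sample was present. Because only genes called by the authors are listed, genes outside the table were not analysed here, and no number of changed genes is claimed.

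Depth per library is unknown, since the values carry no read counts and listed genes are only part of a library. Sums over the listed genes ranged from 25083 to 39465 and are no measure of depth. No interval for counting error is therefore given, and the precision of each value rests on the spread of 3 libraries per group.

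Before the data were examined, the groups, the tests, the alternatives, 22 gene lists and the rule for naming genes were fixed. Values were transformed as log2(value + 1), which understates the change of genes with low values, and used as deposited. Genes with a mean of at least 1 in 1 or both groups were tested with limma 3.58.1 in R 4.3.3, with a trend of variance on mean expression and 1 estimate of spread for both groups. The p-values were adjusted by the Benjamini-Hochberg method over the 499 listed genes that passed this filter, with a threshold of 0.05. The authors selected the listed genes on the same 6 libraries, so this test only asks how far each listed change exceeds the spread between libraries. Its adjusted p-values can be smaller than they would be among all genes. SMAD7, IL6 and CXCL8 were also compared with a 2-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1.

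The direction of a gene list was tested with a 2-sided Fisher's exact test of its members listed higher or lower against the other listed genes, for lists with at least 5 listed members, adjusted by the Benjamini-Hochberg method over those lists. Fisher's exact test treats genes as independent, while genes of a list can vary together in the same 6 libraries. Its p can therefore be too small, and it does not measure the spread between libraries. Set tests that need all genes were not run. To compare a list or family with its level, 10000 random lists were drawn, each member replaced by 1 of up to 60 neighbouring listed genes by mean expression value that lay outside the list. Genes were named if they stood in the series title. Also named were the 10 highest and 10 lowest limma log2 fold changes among genes with a symbol, adjusted p under 0.05, no overlap between the groups and a mean of at least 1 in the higher group. Up to 4 passing members of each list with the smallest adjusted p were added, as were the 5 higher and the 5 lower genes with the smallest adjusted p. This rule named 40 genes, and any other gene in the text was chosen after its values were seen. A listed gene is not reported here and was left out of the gene families grouped by symbol, so the family counts do not cover every listed gene. Gene descriptions were looked up by symbol in a RefSeq gene table of assembly F.catus_Fca126_mat1.0, in which all 633 symbols were found. Because the authors' build is not named, coordinates and transcript lengths were not used here.

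The authors' fold changes were not the ratios of the deposited group means. Library factors were therefore fitted, 1 per library, so that the scaled group means matched the authors' log2 fold changes as closely as possible. This rescaling was chosen after seeing the data. Its target, the authors' fold changes, also served to select the listed genes. Passing calls on this scale are therefore partly built in. The group difference between the factors was well fixed by the data, while the factors of single libraries were not. The alternatives fixed beforehand were median-centred libraries, no low-value filter, a minimum mean of 5, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, a threshold of 0.01, a minimum absolute log2 fold change of 1, and the authors' own fold changes. The limma step was tested on simulated data for the comparison of DOX+PeptideE with DOX, with 454 genes tested, of which 200 had been changed. It called 94% of the genes changed by 0.6 on the log2 scale, 94% of those changed by 1, and 1.2% of the unchanged genes. Both simulated groups were given the spread of the DOX libraries, raised to at least its median over genes. These shares therefore do not hold for genes that spread more with peptide E. Fits other than limma were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.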

Results

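Gene expression was measured by polyA RNA-seq in PETCC2610, a feline kidney cell line, after senescence had been induced with DOX. Senescent cells stop dividing and release inflammatory proteins, the senescence-associated secretory phenotype (SASP). There were 3 libraries of cells with DOX alone and 3 of cells that also received peptide E. Cells without DOX were not analysed here. The depth of the libraries is unknown, and the analysis covers the 633 genes in the authors' deposited table, all selected by the authors as differing between these 6 libraries. Of these genes, 293 were listed higher with peptide E and 340 lower. The groups did not overlap in 482 of them, against 10% of genes by chance, but the authors' selection favours such genes.

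The comparison asks which listed transcripts differ with peptide E among cells given DOX. Without cells lacking DOX, no change can be placed as towards or away from the state before senescence. The series title names SMAD7, SMAD3, IL6 and CXCL8. SMAD7, an inhibitor of TGF-beta receptor signalling, rose from an expression value of 5.18 ± 0.485 (SD, n = 3) with DOX to 9.59 ± 3.33 (SD, n = 3) with peptide E. The limma log2 fold change was 0.73 with a standard error of 0.22 (Benjamini-Hochberg adjusted p = 0.0139). IL6, an inflammatory cytokine, fell from 33.2 ± 3.07 to 24.6 ± 2.83 (SD, n = 3 each). Its limma log2 fold change was -0.42 with a standard error of 0.16 (adjusted p = 0.0315). CXCL8, which attracts neutrophils, fell from 1143 ± 98.1 to 843 ± 158 (SD, n = 3 each), a limma log2 fold change of -0.45 with a standard error of 0.17 (adjusted p = 0.0331). All 3 peptide E libraries lay above all 3 DOX libraries for SMAD7, and below them for IL6 and CXCL8. SMAD3 is not among the listed genes, and phosphorylated SMAD3 is a protein state that RNA-seq does not measure. The 2-sided exact permutation test gave p = 0.1 for each of these 3 genes, the smallest value that 3 against 3 libraries allow. The study chose these genes on the same samples, so they are not independent evidence.

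With 1 library fewer, the signs could not change, since the groups did not overlap in these genes, but several calls were lost. The log2 fold change was 0.73 for SMAD7 without peptide E replicate 2, against 0.73 with all libraries. It was -0.40 to -0.36 for IL6 and -0.52 to -0.29 for CXCL8 in the fits that lost their calls. In limma with Benjamini-Hochberg adjustment, SMAD7 had an adjusted p of 0.0523 without peptide E replicate 2. For IL6 the limma adjusted p was 0.125 without peptide E replicate 2, 0.0934 without DOX replicate 2 and 0.12 without DOX replicate 3. For CXCL8 it passed the threshold with all libraries and without peptide E replicate 1, and was 0.0656 without peptide E replicate 2, 0.107 without peptide E replicate 3, 0.0668 without DOX replicate 1, 0.067 without DOX replicate 2 and 0.138 without DOX replicate 3 (limma).

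The list of SASP cytokines and chemokines, with 35 symbols, had 8 listed members, and all 8 were listed lower with peptide E. They were IL6, CXCL8, CXCL10, CCL8, CSF3, IL18, HGF and GDF15. Among the other listed genes 332 were lower and 293 higher (Fisher's exact test, p = 0.00867, Benjamini-Hochberg adjusted p = 0.0173 over 2 lists). This p takes the 8 genes as independent and can be too small if they vary together. All 7 members tested by limma were lower. Of them 6 passed the threshold over all genes tested, and 6 when adjusted over the list alone. Of all 257 tested genes listed lower, 118 passed. CXCL10, a chemokine induced by interferon, fell from 31.9 ± 5.39 to 21.2 ± 1.62 (SD, n = 3 each), a log2 fold change of -0.56. CCL8, a monocyte chemoattractant, fell from 14.1 ± 0.211 to 10.2 ± 0.539 (SD, n = 3 each), a log2 fold change of -0.43. GDF15, a stress-induced cytokine, fell from 8.47 ± 0.979 to 5.78 ± 0.96 (SD, n = 3 each), and IL18, an inflammasome-processed cytokine, fell from 221 ± 29.3 to 163 ± 33.4 (SD, n = 3 each) with groups that overlapped. CSF3 was at 3.21 with DOX and 2.29 with peptide E (limma adjusted p = 0.093), and HGF, at 0.973 and 0.62, was below the filter. IL6 and CXCL8 were chosen by the study, and without them the other 6 members gave a raw p of 0.0331 and an adjusted p of 0.065 over 2 lists in Fisher's exact test.

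**Figure D1:**
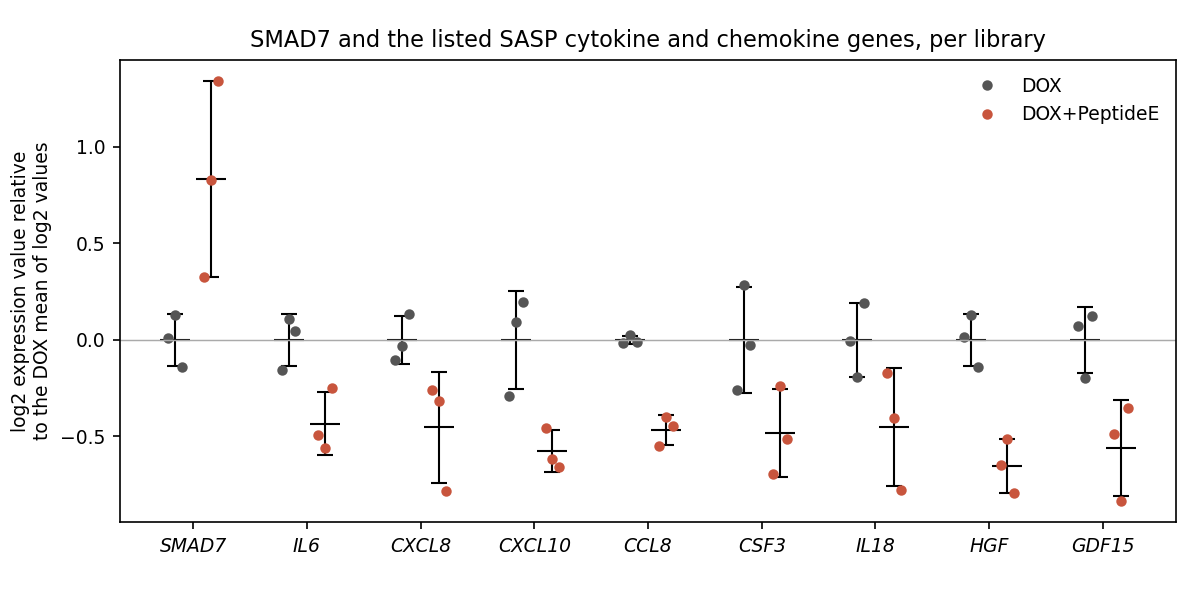
Expression values of SMAD7 and of the 8 listed SASP cytokine and chemokine genes in each library, on a log2 scale relative to the mean log2 value of the DOX libraries. Points are libraries, horizontal marks are means and bars are SD (n = 3 per group), and the peptide E libraries lie above the DOX libraries for SMAD7, while the mean of each of the 8 SASP genes lies below.

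The list of tubular epithelial markers had 5 listed members, all lower, out of 31 symbols. Fisher's exact test against the other listed genes gave a Benjamini-Hochberg adjusted p of 0.065, the smallest that 5 members, all lower, can give here, so this test could not pass for lower genes. All 5 genes tested by limma were lower, but only the keratins KRT18, KRT7 and KRT19 passed the threshold, and 3 genes passed when adjusted over the list alone. KRT18, an intermediate filament protein of simple epithelia, went from 589 ± 70.3 to 369 ± 63 (SD, n = 3 each; limma log2 fold change -0.68, adjusted p = 0.00752). KRT7 went from 415 to 285 and KRT19 from 2.60 to 1.59. The water channel gene AQP1 was at 2.98 and 2.19 (limma adjusted p = 0.0897), and the tubular injury marker HAVCR1 had a limma log2 fold change of -0.16 (adjusted p = 0.405). Without peptide E replicate 1, 4 of the 5 were lower and the adjusted p of Fisher's exact test was 0.373.

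Of the other lists, 11 had 1 to 4 listed members and were not tested as groups. These include the study's title genes and the TGF-beta and SMAD pathway list, in which SMAD7 was the only listed gene. The immediate early genes EGR1 and FOS, transcription factors induced by growth signals, rose. EGR1 went from 6.31 ± 0.128 to 16.5 ± 4.55 (SD, n = 3 each; limma log2 fold change 1.23, adjusted p = 0.00315) and FOS from 6.81 ± 0.504 to 14.6 ± 3.03 (SD, n = 3 each; limma log2 fold change 0.98, adjusted p = 0.0051). The third listed member, DUSP2, was at 0.577 and 0.247 and was below the filter. In the proliferation and lamina list, MKI67, the gene of the proliferation marker Ki-67, was the only one of 39 symbols that was listed. It rose from 12.5 ± 0.846 to 26.4 ± 7.63 (SD, n = 3 each; limma log2 fold change 0.98, adjusted p = 0.00741). In the list of p53 targets and cell cycle arrest genes, MDM2, whose product degrades p53, fell from 322 ± 23.3 to 234 ± 15.4 (SD, n = 3 each), and no other of the 26 symbols was listed.

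Among extracellular matrix genes, COL12A1 rose from 11.6 ± 0.281 to 25.3 ± 9.51 and FBN1, the gene of fibrillin, from 12.6 ± 0.0306 to 25.4 ± 9.48 (SD, n = 3 each). SPP1, which encodes osteopontin, fell from 104 ± 7.94 to 81 ± 8.08 (SD, n = 3 each; limma adjusted p = 0.0414), and COL6A1 was below the filter at 0.13 and 0.0367. The interferon response list had ISG15 and CXCL10, both lower. ISG15, a ubiquitin-like protein, fell from 1968 ± 255 to 1253 ± 310 (SD, n = 3 each; limma log2 fold change -0.67, adjusted p = 0.0118). IGFBP6, the only listed SASP protease or regulator, fell from 203 to 138, and S100A4, the only listed mesenchymal marker, from 257 to 161. NPC1, a lysosomal cholesterol transporter and the only listed member of the lysosome and autophagy list, rose from 3.87 to 7.77. ERN1, a sensor of unfolded proteins and the only listed gene of the unfolded protein and ATF4 list, rose from 0.94 to 1.82. Another 9 lists had no listed member: NF-kB feedback, NRF2 antioxidant response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, endothelial markers, immune cell markers, mitochondrially encoded genes, and apoptosis and survival. Genes of these lists were not analysed here. Several of these limma calls were also lost with 1 library fewer. Those of CXCL10, CCL8, GDF15, IGFBP6, SPP1, ISG15, ERN1, KRT7 and KRT19 were lost without peptide E replicate 2, at adjusted p of 0.0521 to 0.151, and each of them also without 1 or more other libraries. Without peptide E replicate 2 the log2 fold changes were -0.64 to -0.37 in the 8 genes that fell and 0.52 in ERN1, against -0.67 to -0.36 and 0.53 with all libraries. CCL8 lost its call without each of 4 libraries and SPP1 without each of 5, all but peptide E replicate 3. The call of MDM2 was lost without DOX replicate 2 (limma adjusted p = 0.055) or DOX replicate 3 (0.0742). That of ERN1 was also lost after median-centring (limma adjusted p = 0.0888), where its log2 fold change was 0.23.

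Beyond the lists, the lowest limma fold changes among genes with a symbol and no overlap between the groups were in HBA1, a globin subunit gene, and MYL7, an atrial myosin light chain gene. HBA1 fell from 21.6 ± 0.727 to 9.06 ± 1.54 (SD, n = 3 each; limma log2 fold change -1.18, standard error 0.16, adjusted p = 0.00125). MYL7 fell from 158 ± 11.8 to 70.1 ± 5.24 (SD, n = 3 each; limma log2 fold change -1.16, standard error 0.14, adjusted p = 0.00115). The muscle genes MUSTN1 and TNNI2, the gastrokine gene GKN1, the keratin gene KRT15, the calcium-binding protein gene S100A2, and FAM71F2, TMED6 and SBSN also fell, with limma log2 fold changes from -0.90 to -0.72. S100A2 was the most abundant of these, at 794 ± 32.2 and 471 ± 38.2 (SD, n = 3 each), and LOC109497776, an uncharacterized locus, fell from 58.8 to 34.2. The limma call of TMED6 was lost without DOX replicate 2 (adjusted p = 0.0568) or replicate 3 (0.0582), and that of SBSN without peptide E replicate 2 (0.0515) or DOX replicate 3 (0.0707). FAM71F2 kept its call, but its limma log2 fold change was -0.49 without DOX replicate 3, against -0.83 with all libraries. The order of the lowest genes depended on the pseudocount. At 0.1, FAM71F2 lay below HBA1 (limma log2 fold change -1.49 against -1.26) and TNNI2 below MYL7 (-1.19 against -1.17). Globins, keratins and S100 genes belong to families of similar sequence, so their values are uncertain where reads could be shared.

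Among genes with a symbol and no overlap between the groups, the highest limma fold changes after EGR1 were in GRIP1, a synaptic scaffold gene that rose from 0.63 ± 0.0721 to 2.42 ± 0.597, and KCTD12, which rose from 2.22 ± 0.288 to 5.69 ± 1.35 (SD, n = 3 each). COL12A1, FOS, SRRM2, a splicing cofactor gene, MKI67, PXDN, a matrix peroxidase gene, IGF2R and GRIN3A followed, with limma log2 fold changes of 0.96 to 0.99. PXDN was the most abundant of them and rose from 33.7 ± 1.36 to 67.8 ± 14.9 (SD, n = 3 each). This order also depended on the pseudocount. At 0.1, GRIP1 lay above EGR1 (limma log2 fold change 1.77 against 1.34). At 5, GRIP1 (0.40) and KCTD12 (0.56) lay below PXDN (0.89). At the pseudocount of 1, some loci without a gene symbol lay above EGR1. A histone H2A-like locus, LOC101086721, rose from 0.85 to 3.65, a limma log2 fold change of 1.31. A histone H3.1 locus, LOC101093269, was listed at 0 in all 3 DOX libraries and at 2.77, 1.66 and 1.12 with peptide E. Histone loci are near-identical copies, and these values are uncertain.

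Across the listed genes, 499 were tested by limma, 242 of them listed higher and 257 lower. An adjusted p of 0.05 was passed by 355, of which 237 were higher and 118 lower. With library factors recovered from the authors' fold changes, 474 passed, 228 higher and 246 lower. Higher genes therefore made up 66.8% of the calls as deposited and 48.1% after rescaling. The authors selected genes by fold change on their own scale. There the log2 fold changes lay below the deposited ones by a median of 0.27 in 196 genes. Genes listed higher thus had to change more on the deposited scale than genes listed lower. The excess of higher calls as deposited is therefore at least partly built in by this selection. Without peptide E replicate 2 the count as deposited fell to 180 (38 lower). The lower genes numbered 49 without DOX replicate 1 and 44 without DOX replicate 3. In the authors' deposited table, 359 of the 633 genes had an adjusted p under 0.05. The authors' deposited table gave 160 genes an adjusted p of exactly 1 despite unadjusted p-values down to 0.000556. Among them were TNNI2, FAM71F2, SBSN, GRIP1 and both histone loci. The largest other adjusted p in the authors' deposited table was 0.19, so a value of 1 does not follow from the adjustment used for the other genes. These 160 genes were low, with a median of 0.452 in the higher group against 6.52 for the rest, and why they carry a 1 is not given in the sources used here.

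The 2 scales differed by a near-constant amount. In 196 genes with a mean of at least 5 in both groups, the log2 ratio of deposited means exceeded the log2 fold change of the authors' deposited table by a median of 0.27. After rescaling, the limma log2 fold changes of the tested genes moved by a median of -0.23. The 3 title genes stood at 0.48 for SMAD7, -0.68 for IL6 and -0.73 for CXCL8. The authors' deposited table gives log2 fold changes of 0.59, -0.71 and -0.69 for them. KIF13B and LOC109498258 were exceptions with opposite signs on the 2 scales. KIF13B was listed higher at 0.73 in the authors' deposited table while its deposited values were 8.24 with DOX and 7.86 with peptide E.

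**Figure D2:**
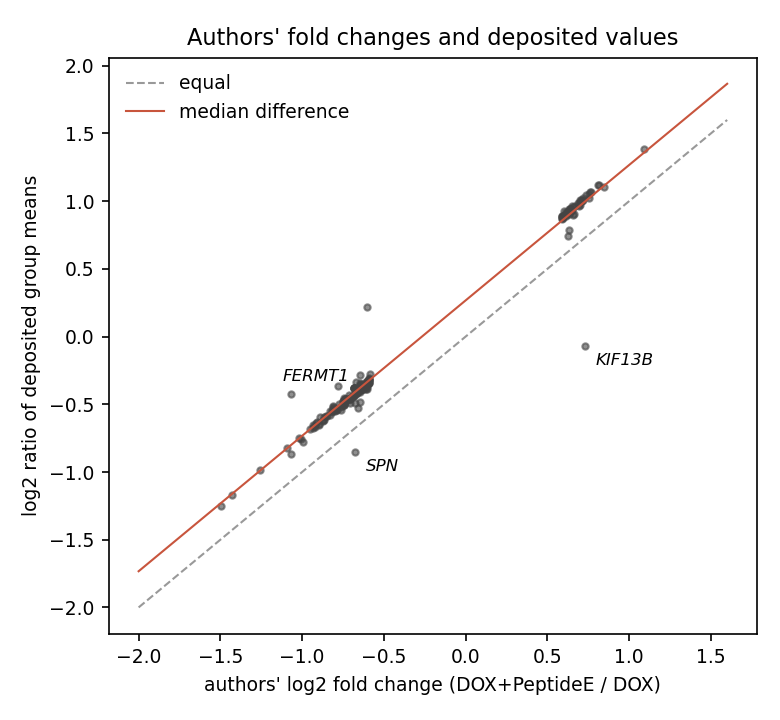
Log2 ratio of the deposited group means (y axis) against the authors' log2 fold change (x axis), both of peptide E over DOX, for the 196 genes with a mean of at least 5 in both groups. Each point is a gene, the dashed line marks equality, and the solid line marks the median difference of 0.27, which nearly all genes follow and KIF13B, SPN, FERMT1 and the unlabelled LOC109498258 leave.

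Direction went with abundance, and whether it also went with transcript length is not known, since lengths were not used here. Of the 148 listed genes with an overall mean of at least 10, 113 were lower and 35 higher, and all 37 genes with a mean of at least 100 were lower, among them ISG15, CXCL8, MDM2, KRT18 and S100A4. A locus of 18S ribosomal RNA, LOC111557932, rose from 2.20 ± 0.085 to 4.43 ± 0.787 (SD, n = 3 each; limma log2 fold change 0.75, adjusted p = 0.00752) in libraries captured by polyA. The peptide E libraries also differed from one another. The median log2 deviation from the DOX mean over the genes listed higher was 0.39 in peptide E replicate 1, 0.80 in replicate 2 and 1.03 in replicate 3, and over the genes listed lower it was -0.33, -0.42 and -0.51. Replicate 1 also held the smallest value among the peptide E libraries for SMAD7, EGR1, FOS, MKI67, COL12A1 and FBN1.

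**Figure D3:**
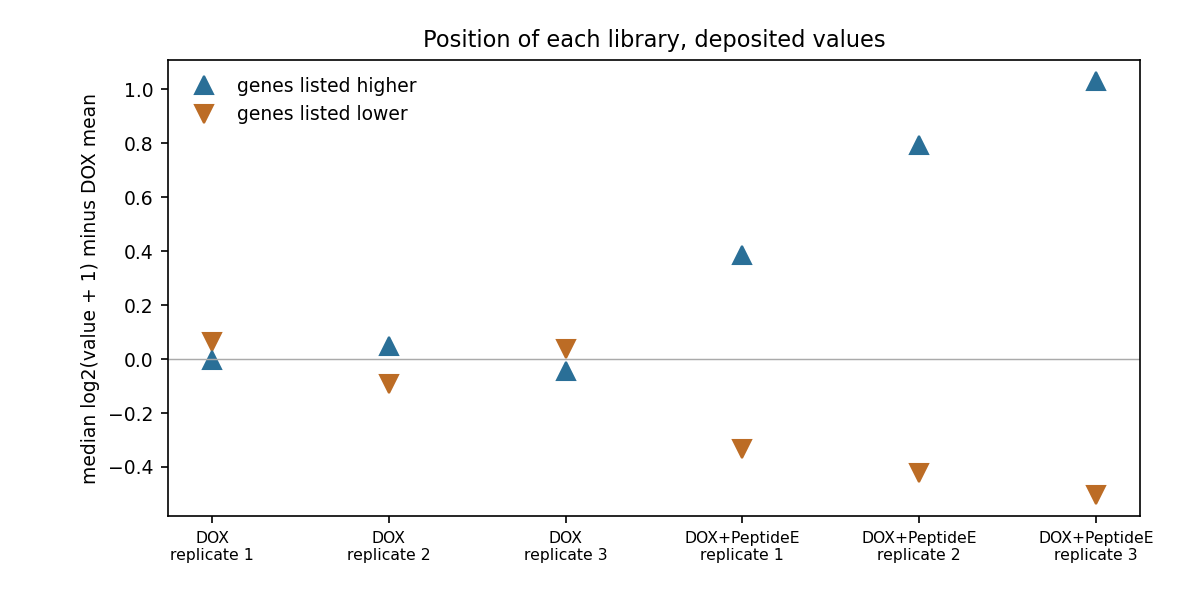
Median deviation of log2(value + 1) from the mean of the DOX libraries in each of the 6 libraries, for tested genes listed higher (upward triangles) and lower (downward triangles) with peptide E. The DOX libraries lie near 0, and peptide E replicate 1 lies nearest to them in both gene sets, at 0.39 and -0.33.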

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

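The rescaling with recovered library factors, the changes of members of the SASP list, and the use of limma directions for the lists (0.0305 for SASP, 0.0618 for tubular markers) were chosen after seeing the data, and the other settings were planned. The choice of a count-based normalization and the set tests with estimated correlation were not run, since the table holds neither counts nor all genes. The signs of all 40 named genes were the same in every limma setting that tested them. No named gene overlapped between the groups, so in limma only median-centring or the recovered factors could have changed a sign. All 40 passed with recovered factors, and after median-centring only ERN1 lost its call. The recovered factors were fitted to the fold changes on which the listed genes had been selected. Passing with them is therefore no independent check. Against 355 genes, 203 passed with a minimum mean of 5 (118 higher), 150 at an adjusted p of 0.01 (126 higher, 24 lower) and 10 with an absolute log2 fold change of at least 1 (6 higher, 4 lower), where fewer genes can pass by construction. The number of lower genes was 250 after median-centring and 246 with recovered factors against 118. Median-centring used only the tested genes, 242 listed higher and 257 lower, so it favours an even split by construction. The uneven split as deposited is also partly built in, since the authors' fold threshold was set on their own scale. Leaving out single libraries gave 180 to 413 genes, 142 to 240 higher and 38 to 173 lower. The fewest passed without peptide E replicate 2 (180, with 142 higher and 38 lower), and 49 and 44 lower genes without DOX replicates 1 and 3. In median deviation, peptide E replicate 2 lay between replicates 1 and 3 in both gene sets, so leaving it out kept the libraries furthest apart. The standard error rose from 0.22 to 0.28 for SMAD7, from 0.16 to 0.19 for IL6 and from 0.17 to 0.22 for CXCL8. It also rose in these genes without each DOX replicate. The cause was not tested further. SMAD7 (0.73), IL6 (-0.42) and CXCL8 (-0.45) kept their signs in every setting but missed the thresholds of 0.01 and of 1 in log2. Their ranges without single libraries were 0.50 to 0.96, -0.51 to -0.36 and -0.55 to -0.29. The limma call of SMAD7 was lost without peptide E replicate 2 (adjusted p = 0.0523), that of IL6 without peptide E replicate 2 or DOX replicates 2 or 3 (up to 0.125), and that of CXCL8 without any library but peptide E replicate 1 (up to 0.138). The SASP list kept its Fisher call in every setting that could test it (0.0149 to 0.0316 without single libraries) except without IL6 and CXCL8, at 0.065, where fewer genes were tested. The thresholds of 0.01 and of 1 in log2 left too few members to test. Fisher's exact test used directions alone, and at most 8 tested genes changed sign in any setting. The call could therefore hardly change while the members stayed the same. The tubular list gave 0.0615 to 0.373, the latter without peptide E replicate 1, but 5 members all lower could not have passed in any of these settings. Of the 40 named genes, 15 lost their limma call without 1 or more libraries. Same-numbered libraries of the 2 groups correlated at 0.336, -0.042 and -0.092 in their deviations, so the numbers were not taken as pairs; with the replicate block 362 genes passed, 344 of them shared, the title genes kept their calls at 0.73, -0.42 and -0.45, the lists gave 0.0305 and 0.0618, and of the named genes only SPP1 lost its call. Not every library correlated best with its own number. Depth is unknown, so what counting error limits cannot be stated.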

Other observations

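The family groupings, the comparison of scales and both tests on peptide E replicate 1 were chosen after the result was seen. The regrouping of libraries and the abundance tests were set before their own results were seen, those of the families only after the families had been picked by direction. Several families of related genes were listed in 1 direction. Chromatin regulators, among them the histone methyltransferases KMT2A and KMT2D, the acetyltransferases EP300 and CREBBP, and ARID1A, were listed higher in 15 of 15 cases (Fisher's exact test against the other listed genes, Benjamini-Hochberg adjusted p = 4.73e-05 over 6 families). In limma, 14 of the 14 tested passed. Of all 242 tested genes listed higher, 237 passed, so this count is not particular to the family. EP300 went from 2.33 ± 0.161 to 5.07 ± 2.08 and ARID1A from 3.83 ± 0.405 to 7.65 ± 2.02 (SD, n = 3 each). The basement membrane genes LAMB1, LAMC1, COL4A3 and COL4A4 rose, but collagens and laminins together, with 5 of 6 listed higher, missed the threshold (adjusted p = 0.101). Level-matched random lists of listed genes held as many higher genes in 0.0% of 10000 draws for chromatin regulators and in 1.05% for collagens and laminins. The families were picked after the directions had been seen, so these tests are not independent evidence and exclude nothing. Some of the genes listed higher, such as KMT2A, KMT2D, EP300, COL12A1, FBN1 and MKI67, are known for long transcripts, and some listed lower, such as ribosomal protein, S100 and cytokine genes, for short ones. These examples were picked after their directions had been seen, and no count or test of length was made. Whether transcript length or RNA integrity accounts for either direction stays open, since lengths were not used here and the 18S ribosomal RNA locus LOC111557932 also rose.

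Keratins, sarcomere genes and ribosomal proteins were each listed lower in 7 of 7 cases (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0254 for each), on deposited, median-centred and rescaled values alike wherever tested. Abundant listed genes were mostly lower, so the split of a family of abundant genes follows in part from its level. Level-matched random lists were all lower in 55.7% of 10000 draws for ribosomal proteins, 1.74% for keratins and 1.99% for sarcomere genes, so the direction of the ribosomal proteins is that of other listed genes of their level. Transcript length and RNA integrity stay open for these families too. In limma 7 keratins, 5 of 6 tested sarcomere genes and 4 of 7 ribosomal protein genes passed as deposited, and 7, 6 and 7 with recovered library factors. Of all 257 tested genes listed lower, 118 passed as deposited. With the recovered factors 474 of the 499 tested genes passed, so passing there says little about a family. RPS24 went from 4985 ± 823 to 3623 ± 859 and RPS19 from 4983 ± 440 to 3709 ± 634 (SD, n = 3 each). Ribosomal protein genes have many processed copies, so their values are uncertain. The respiratory chain genes, with 5 of 5 lower, had an adjusted p of 0.0779, but 5 members all lower cannot pass this test. Matched lists were all lower in 35.7% of draws, and 1 of 5 passed in limma as deposited and 5 of 5 with recovered library factors. The C-C motif chemokine 7 locus LOC101096931, outside the list by symbol, went from 2.45 ± 0.325 to 1.17 ± 0.261 (SD, n = 3 each; limma adjusted p = 0.00781).

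Peptide E replicate 1 lay nearest to the DOX libraries in 225 of 242 tested genes listed higher and in 132 of 257 listed lower. A scaling error of that library alone would move it in 1 direction in both sets. Against replicates 2 and 3 it was displaced by -0.49 in the higher genes and by 0.113 in the lower genes (95% interval over genes 0.07 to 0.161), and the signs were also opposite after rescaling, which argues against such an error as the whole cause. A smaller response of 1 common kind stays open: its shares differed between the sets by -0.276, but a scaling of the same library on top of it can equalise them, so a smaller response with and without such a scaling cannot be told apart. Whether culture, dose or RNA integrity set replicate 1 apart was not tested, since the labels give no such value per library.

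The offset between the authors' fold changes and the deposited means is consistent with a different library scaling in the authors' test. With 1 factor per library the median absolute log2 difference fell from 0.27 to 0.00593, and 92.9% of 196 genes came within 0.05. The group difference of the factors was 0.27 (bootstrap interval over genes 0.27 to 0.28). After the factors, 4 genes stayed off by more than 0.25, KIF13B, SPN, FERMT1 and LOC109498258. No biological explanation was tested for these genes.

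Of the 8 listed SASP members, 6 lay above the median level of the listed genes, and abundant listed genes were mostly lower. Random lists of 8 genes matched on level held 5.15 lower genes on average and were all lower in 1.77% of 10000 draws. The 8 members include IL6 and CXCL8, which the study chose on these samples, and no draws were made without them. The draws therefore cannot decide whether abundance alone accounts for the split. A peptide effect on SASP transcripts is a hypothesis, and transcript length and RNA integrity stay open because lengths were not used here. Of the 10 splits of the 6 libraries into 3 and 3, 1 passed as many listed genes as the real split, which is the real split itself with 355, and the highest other passed 2. With 10 splits no share under 0.05 can be reached, and the genes had been selected on the real split.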
